A study of Mus musculus with 19 samples.

How the data were processed

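Messenger RNA bound to tagged ribosomes was measured by RNA sequencing in 19 libraries of mouse brain astrocytes. The tag is an EGFP-labelled ribosomal protein L10a expressed under the astrocyte gene Aldh1l1, and tagged ribosomes were pulled down before RNA extraction (translating ribosome affinity purification, TRAP). The labels give 4 groups: 8 metestrus, 3 proestrus, 4 estrus and 4 male libraries, and 3 batches named 2, 3 and 4. Batch 2 held 2 metestrus, 2 proestrus and 3 estrus libraries, batch 3 held 1 of each of these stages, and batch 4 held 5 metestrus and 4 male libraries. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between libraries. Replicate numbers follow the order of the deposited samples and serve as names.

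The deposited values are on a log2 scale, with 21749 genes in 19 columns and a range from -5.12 to 19.00. Per the labels, the submitters' processing notes name STAR, Salmon, edgeR and the genome build GRCm39, without versions or the order of steps. The log base was settled from the values: powers of 2 sum to 1.98e7 to 2.56e7 per library, and powers of the natural base to 1.14e9 to 1.66e9. The pseudocount, scaling and filters of the authors are not given in the sources used here. After each gene was centred the 19 columns spanned 14 dimensions in place of 18, and after the 4 groups were fitted they spanned 11 in place of 15. The deposited values therefore lack 4 directions of variation between libraries, taken out with the group means kept. Of the pair of batch directions, 98.6% of the first and 9.95% of the second lay in the removed space. The sequencing depth is unknown, and no interval that needs counts is given.

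The main tests were set before the data were examined, as were the gene lists, the comparisons and the rule for the genes to name. The planned filter for counts was replaced by the one given below, and the permutation test of list means was not in the plan. Their plan assumed counts, or values to which a pseudocount of 1 would be added before the log, and the deposited log2 values were used as they are. Genes with a value of at least 3.32 (10 before the log) in at least 3 libraries were tested, which left 20644 genes (94.9%). limma 3.58.1 in R 4.3.3 fitted group and batch to all 19 libraries (limma-trend with a robust variance prior), and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes at a threshold of 0.05. The model counts 13 residual degrees of freedom, whereas the rank of the values allows 11, so its p-values are somewhat too small. Unchanged groups were simulated 10 times with and 10 times without batch effects, and 4 directions were removed with the groups kept. Over the contrasts, the median share of genes with an unadjusted p under 0.05 was 7.31% to 10.1%, and at most 10 genes passed the threshold. Simulated genes varied independently with equal spread in all libraries, and the authors' own removal is unknown. The simulations are therefore a limited guide to false calls in the real values. A second model adds the removed directions that batch does not span and counts 11 degrees of freedom. It was chosen after the rank was seen, and its adjusted p-values stand beside the main ones where they end the call of a gene named as past the threshold.

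With batch in the model, fold changes between the stages rest on the libraries of batches 2 and 3, and those of males against metestrus on batch 4. The metestrus libraries of batch 4 enter the stage comparisons through the estimate of spread alone. Males share no batch with proestrus or estrus, and these contrasts are linked through metestrus. Fold changes are given as the first group over the second with the standard error of the fit (SE), and group levels as mean log2 value with the standard deviation (SD) between libraries.

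The 35 gene lists cover cell type markers, astrocyte functions, hormone responses, metabolism and sex-linked genes. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with an estimated correlation and with fry, for change in 1 direction and in mixed directions. Members of a list were also adjusted over the list alone. A list's genes are not independent samples. In males against metestrus the mean of each list was compared within batch 4 by an exact two-sided permutation test over all 126 splits. Directions were removed from the values with the real groups kept, which favours the real split. The p-values of this test may therefore be too small. Of the listed symbols, 27 were not among the genes tested, and the genes called measured are those tested. A missing symbol can reflect the filter or another name for the gene as well as absence from the file. Gene identities are those of the file, where 26 symbols belong to more than 1 gene and 1841 genes lack a symbol of their own. No coordinates are given, because the annotation at hand is of another build than the one named by the authors.

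The rule for named genes took, for each contrast, up to 10 higher and 10 lower genes past the threshold with the largest fold changes among annotated genes with an average log2 CPM of at least 1, or up to 5 each way for males against proestrus and against estrus. It added up to 4 members of each list past the threshold, the 10 smallest p-values where fewer than 10 genes passed, Xist and the Y-linked genes in contrasts with males, and Aldh1l1, Gfap, Esr1, Esr2, Gper1 and Pgr in every stage contrast. A further planned gene is not reported here. The shift from deposited values to log2 CPM was 4.54. In a test on simulated data with 200 changed genes per contrast, the main model found 10.4% to 38.8% of changes of 1 log2 unit, 41.8% to 61.2% of changes of 2 and 72.7% to 83.3% of changes of 4. False calls were 35 of 147 for estrus against proestrus, 18 of 137 for males against metestrus, 9 of 121 for proestrus against metestrus and 3 of 108 for estrus against metestrus. There were 0 among the 95 and 88 simulated calls of the contrasts that link males to proestrus and to estrus. Alternatives changed the filter, the threshold, the use of batch, the libraries in the fit, the scaling and the model of spread, and left out each library in turn.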

Results

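Ribosome-bound messenger RNA, captured with a tag expressed in cortical astrocytes, was profiled in female mice at 3 stages of the estrous cycle and in males. Females were collected at 09:00 in metestrus (8 libraries), proestrus (3) or estrus (4). A further 4 libraries came from males, whose collection hour is not given in the sources used here. Sequencing depth is unknown. The deposited log2 values, taken back from the log scale, summed to 2.31e7 ± 1.29e6 per library in metestrus (SD, n = 8) and 2.22e7 ± 1.01e6 in proestrus (SD, n = 3). The sums were 2.32e7 ± 2.37e6 in estrus (SD, n = 4) and 2.46e7 ± 1.53e6 in males (SD, n = 4). Across genes, the median correlation of log2 values between libraries of a group was 0.953 in metestrus, 0.944 in proestrus, 0.919 in estrus and 0.948 in males. Between libraries of different groups it was 0.915. The first principal component held 21.5% of the variance and placed the proestrus and estrus libraries (46.8 to 95.9) apart from the metestrus and male libraries (-71.3 to -16.0). The values lack directions taken out with the group means kept, which favours separation by group. These correlations and this component therefore do not measure how far the groups differed before that removal.

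Astrocyte transcripts were abundant in all 4 groups, and transcripts of other cell types were present beside them. The mean of 22 astrocyte markers was 13.81 ± 0.22 in metestrus (SD, n = 8) and 13.70 ± 0.03 in proestrus (SD, n = 3). It stood at 13.71 ± 0.31 in estrus (SD, n = 4) and 13.97 ± 0.09 in males (SD, n = 4). Slc1a2, the main glutamate transporter of astrocytes, averaged 15.73 in metestrus and Aldh1l1, whose regulatory sequence drives the tag, 12.05. The mean of 18 neuron markers was 11.87 ± 0.11 in metestrus (SD, n = 8) and 11.90 ± 0.15 in proestrus (SD, n = 3). In the other groups it was 11.94 ± 0.16 in estrus (SD, n = 4) and 11.88 ± 0.11 in males (SD, n = 4). Snap25, a protein of neuronal synaptic vesicle fusion, averaged 15.56 in metestrus. The samples hold no library of unpurified tissue, so enrichment was not measured. Changes of single genes below therefore cannot be assigned to astrocytes rather than to other cells. Markers of oligodendrocytes averaged 9.74 ± 0.06 in metestrus (SD, n = 8), and the microglial receptor Cx3cr1 averaged 7.48 there. Rpl10a, the ribosomal protein gene whose product carries the tag, averaged 12.38 ± 0.13 in metestrus (SD, n = 8) and 12.13 ± 0.23 in proestrus (SD, n = 3). It averaged 11.92 ± 0.24 in estrus (SD, n = 4) and 12.99 ± 0.35 in males (SD, n = 4).

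Proestrus, the stage when estrogen peaks, was compared with metestrus. Esr1 (ENSMUSG00000019768.17), which encodes estrogen receptor alpha, was 14.8-fold lower in proestrus, at 2.38 ± 1.59 (SD, n = 3) against 6.26 ± 0.41 (SD, n = 8). The log2 fold change was -3.89 ± 0.69 (SE, adjusted p = 0.00772), and -4.53 to -2.90 when single libraries were left out. Usp18 (ENSMUSG00000030107.11), which removes ISG15 from proteins and dampens interferon signalling, was 36.3-fold lower, at 0.53 ± 0.65 (SD, n = 3) against 5.75 ± 0.68 (SD, n = 8). Its log2 fold change was -5.18 ± 0.68 (SE, adjusted p = 0.000681), and -5.58 to -4.53 when single libraries were left out. Ccnf (ENSMUSG00000072082.8), the F-box protein cyclin F, fell by 3.86 on the log2 scale (SE 0.58, adjusted p = 0.00194). Trib3 (ENSMUSG00000032715.10), a pseudokinase induced by cell stress, rose from 1.57 ± 0.74 in metestrus (SD, n = 8) to 5.65 ± 1.10 in proestrus (SD, n = 3), with an adjusted p of 0.0373 and of 0.114 once the removed directions were counted. The proestrus means of Esr1, Usp18 and Ccnf and the metestrus mean of Trib3 lay below the minimum of 3.32. The sizes of these changes are therefore uncertain. Of 20644 genes, 204 passed the threshold in limma, 48 higher and 156 lower in proestrus (84 and 89 without Metestrus replicate 3). An unadjusted p under 0.05 was found for 2707, where simulations of unchanged groups with independent genes gave medians of 1532.5 to 1782.5. The call rate was lower among abundant genes: 55 of the 204 (27.0%) had an average log2 CPM of at least 1, as did 65.2% of all tested genes.

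Further genes past the threshold in proestrus were named among those with an average log2 CPM of at least 1. Dnah1, a heavy chain of axonemal dynein, fell by 3.23 (SE 0.51, adjusted p = 0.00312), Cfap69, a cilium and flagellum protein, by 3.16 (SE 0.62, adjusted p = 0.0134). Lca5, the ciliary protein lebercilin, fell by 2.86 (SE 0.50, adjusted p = 0.00772). The zinc finger genes Zfp747l1 and Zfp873 fell by 2.99 (SE 0.43) and 2.80 (SE 0.53), with adjusted p-values of 0.00145 and 0.0107. Ints6l, a relative of an Integrator subunit, fell by 2.67 (SE 0.54, adjusted p = 0.0153). Nwd2os, annotated as an antisense transcript and measured here in a file that does not state strand, fell by 3.12 (SE 0.44, adjusted p = 0.00122). Trmt44, a tRNA methyltransferase, and Prrg1, a membrane protein with a Gla domain, had changes of -3.20 ± 0.73 (SE, adjusted p = 0.0354, and 0.0841 with the removed directions counted) and -4.60 ± 1.10 (SE, adjusted p = 0.0455, and 0.0939). The Prrg1 ranges of both groups overlapped. When single libraries were left out, the Trmt44 change ran from -4.27 to -2.10 and that of Prrg1 from -6.57 to -3.08. The proestrus means of Dnah1, Nwd2os, Trmt44 and Prrg1 lay below the minimum of 3.32. On the higher side were the zinc finger genes Zfp174 at 3.18 ± 0.56 (SE, adjusted p = 0.00772) and Zfp879 at 2.26 ± 0.39 (SE, adjusted p = 0.00722). Fam241a stood at 1.78 ± 0.35 (SE) and the potassium channel Kcnk10 at 1.60 ± 0.36 (SE), with adjusted p-values of 0.0134 and 0.0319 (0.0877 for Kcnk10 with the removed directions counted). Lcmt2 and Spice1 both stood 1.44 higher, with adjusted p-values of 0.0422 and 0.0354, and of 0.112 and 0.103 with the removed directions counted.

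Of the 16 measured genes for sex steroid receptors and neurosteroid synthesis, 1 fell over all genes tested. Adjusted over the list alone 2 fell, Esr1 and the 5-alpha reductase gene Srd5a1 (-1.14, adjusted p = 0.0165 over the list alone). Pgr, the progesterone receptor, did not pass at 0.47 ± 0.25 (SE, adjusted p = 0.441). Gper1, a membrane estrogen receptor, stood at -1.78 ± 1.14 (SE, adjusted p = 0.542) and Esr2 at -0.41 ± 1.54 (SE, adjusted p = 0.942). The astrocyte genes Gfap and Aldh1l1 stood at -0.17 ± 0.21 (SE, adjusted p = 0.798) and -0.10 ± 0.22 (SE, adjusted p = 0.894). Of 21 interferon and antigen presentation genes 1 fell, Usp18, over all genes and adjusted over the list alone, and Irf7 stood at -2.82 (adjusted p = 0.170). Among 26 heat shock and unfolded protein genes 1 rose, Trib3, by both adjustments. Of 12 A1 reactive astrocyte genes 0 passed over all genes, and adjusted over the list alone 1 rose, Gbp2, by 2.62. Of 18 glucocorticoid-responsive genes 0 passed over all genes, and adjusted over the list alone 2 fell, Arrdc2 at -0.98 and Zbtb16 at -0.91. As whole lists, 0 of 35 passed camera at either correlation or fry for 1 direction (lowest adjusted p 0.334, 0.992 and 0.234) while 3 had an unadjusted p under 0.05 in camera. Choroid plexus and ependymal markers, from tissue with ciliated cells, were negative in 10 of 12 at a median of -0.71 (camera adjusted p = 0.530). In limma's fry for mixed directions 3 passed, the interferon (adjusted p = 1.74e-05), sex steroid (0.00638) and glucocorticoid lists (0.0384).

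In proestrus against metestrus the count was 75 (16 higher, 59 lower) with the removed directions counted, and it was 203 (70 higher, 133 lower) with libraries centred on their medians; within batches 2 and 3 alone fold changes were identical by construction and 1 gene passed, Slfn2 at 5.70, named after its value was seen. Without Metestrus replicate 1 the count was 68, without Proestrus replicate 1 it was 82 and without Proestrus replicate 2 it was 126. Without Metestrus replicate 3 it was 173, with 84 higher and 89 lower. Of the 19 genes named by the rule as past the threshold, 7 kept their call in all 11 fits that left out 1 library (Zfp174, Zfp879, Ccnf, Dnah1, Nwd2os, Zfp747l1 and Usp18). Esr1 lost it without Metestrus replicate 1 (-3.60, adjusted p = 0.0502).

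**Figure D1:**
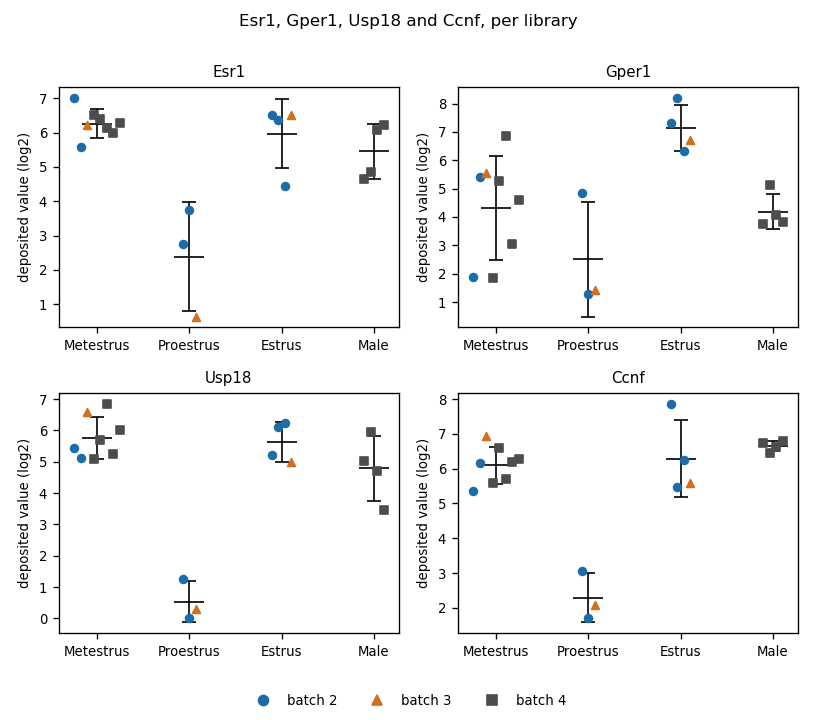
Deposited log2 values of Esr1, Gper1, Usp18 and Ccnf in each library (points, shaped by batch), by group on the horizontal axis, with group means (bars) and SD (error bars). The 3 proestrus libraries lie below every library of the other groups for Esr1 (highest 3.75), Usp18 (highest 1.26) and Ccnf (highest 3.07), while for Gper1 they overlap with metestrus.

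Estrus, the day after the preovulatory hormone surge, was compared with proestrus. Esr1 stood 11.6-fold higher at 5.96 ± 1.0 (SD, n = 4) against 2.38 ± 1.59 (SD, n = 3), a log2 fold change of 3.53 ± 0.64 (SE, adjusted p = 0.00937) that ran from 2.62 to 4.20 when single libraries were left out. Gper1 (ENSMUSG00000053647.5) stood 24.6-fold higher at 7.14 ± 0.80 (SD, n = 4) against 2.51 ± 2.02 (SD, n = 3). Its log2 fold change was 4.62 ± 1.07 (SE, adjusted p = 0.0375, and 0.0860 with the removed directions counted), and 3.90 to 5.92 when single libraries were left out. Usp18 was 34.4-fold higher at 5.63 ± 0.63 (SD, n = 4), with a log2 fold change of 5.10 ± 0.64 (SE, adjusted p = 0.000262). The proestrus means of Esr1, Gper1 and Usp18 lay below the minimum of 3.32, so the sizes of these changes are uncertain. The same holds for Ccnf, Nwd2os, Dnah1 and Trmt44 below. Adra1b (ENSMUSG00000050541.15), an alpha-1 adrenergic receptor, was lower in estrus at 7.02 ± 0.48 (SD, n = 4) against 8.57 ± 0.67 (SD, n = 3), with an adjusted p of 0.0348 and of 0.0903 with the removed directions counted. Of 20644 genes 194 passed in limma, 123 higher and 71 lower in estrus. Of these 75 (38.7%) had an average log2 CPM of at least 1, and among all tested genes 2985 had an unadjusted p under 0.05. Because this contrast and the one of proestrus against metestrus share the 3 proestrus libraries, their results are not independent.

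Genes with an average log2 CPM of at least 1 that rose in estrus over proestrus were Ccnf at 4.00 ± 0.54 (SE, adjusted p = 0.000699), Nwd2os at 3.39 ± 0.41 (SE, adjusted p = 0.000212). So did Cfap69 at 3.27 ± 0.58 (SE, adjusted p = 0.00816), Dnah1 at 2.90 ± 0.48 (SE, adjusted p = 0.00474) and Lca5 at 2.76 ± 0.47 (SE, adjusted p = 0.00586). Trmt44, Smco3, Frmd3 and Zfp119a rose by 3.23, 2.75, 2.67 and 2.67, with adjusted p-values of 0.0262, 0.0482, 0.0291 and 0.0496, and of 0.0680, 0.110, 0.0817 and 0.110 with the removed directions counted. When single libraries were left out, they ranged from 2.22 to 3.66, 1.82 to 3.54, 2.17 to 3.42 and 1.67 to 3.21. Smco3 and Zfp119a each lost the call in 6 of 7 such fits. Tph2, tryptophan hydroxylase of serotonin neurons, stood at 6.87 ± 0.32 in estrus (SD, n = 4) and 4.34 ± 1.16 in proestrus (SD, n = 3), with an adjusted p of 0.0227 and of 0.0671 with the removed directions counted. Lower in estrus were the cadherin Pcdh15 (-2.14 ± 0.51 SE, adjusted p = 0.0468) and the angiotensin-converting enzyme gene Ace (-2.12 ± 0.45 SE, adjusted p = 0.0263). So were glycerate kinase Glyctk (-2.07 ± 0.41 SE, adjusted p = 0.0193) and Aste1 (-2.06 ± 0.41 SE, adjusted p = 0.0177). With the removed directions counted these 4 had adjusted p-values of 0.122, 0.0840, 0.0661 and 0.0646. The pattern receptor Nod1, the orphan nuclear receptor Nr2c1, Trank1 and Lcmt2 fell by 1.79, 1.73, 1.63 and 1.46, with adjusted p-values of 0.0324, 0.0402, 0.0314 and 0.0291, and of 0.0966, 0.110, 0.0817 and 0.0840 with the removed directions counted. Bcl9l, a beta-catenin cofactor in Wnt signalling, fell by 1.37 (SE 0.25, adjusted p = 0.00997).

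Of the 16 sex steroid receptor and neurosteroid genes 2 rose from proestrus to estrus over all genes, and 3 adjusted over the list alone, with Srd5a1 (0.96) as the third. Pgr stood at -0.60 ± 0.23 (SE, adjusted p = 0.220) and Esr2 at 1.78 ± 1.45 (SE, adjusted p = 0.611). The astrocyte genes did not pass either, Gfap at 0.31 ± 0.20 (SE, adjusted p = 0.493) and Aldh1l1 at 0.10 ± 0.21 (SE, adjusted p = 0.864). Among 21 interferon genes 1 rose over all genes, and adjusted over the list alone 2 rose, Usp18 and Ifit1 (2.54). Of 19 calcium and neuromodulator receptor genes 1 fell, Adra1b, by both adjustments. The filament gene Nes stood at -2.94 (adjusted p = 0.0605), and adjusted over its list of 25 process and cytoskeleton genes alone it fell. As whole lists 0 of 35 passed camera (lowest adjusted p 0.0881, and 0.949 with an estimated correlation) or fry for 1 direction (lowest 0.133), while 8 had an unadjusted p under 0.05 in camera. In limma's fry for mixed directions the sex steroid (adjusted p = 0.000221) and interferon lists (4.31e-05) passed. The endothelial and mural list had a median of -0.50 with 13 of 14 genes negative. The choroid plexus and ependymal list had a median of 0.90 with 9 of 12 positive (camera adjusted p = 0.195), and adjusted over the list alone 1 gene rose, Ccdc153 at 1.56. A set of 7 long non-coding RNAs retained in nuclei had a median of -1.44 (camera adjusted p = 0.00115 over the 6 contrasts, and 0.195 with an estimated correlation).

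For estrus against proestrus 52 genes (42 higher, 10 lower) passed with the removed directions counted and 184 higher and 118 lower genes with libraries centred on their medians, whereas within batches 2 and 3 alone 0 passed in limma (2249 had an unadjusted p under 0.05). The count was 66 without Proestrus replicate 1, 83 without Proestrus replicate 2, 304 without Proestrus replicate 3, 123 without Estrus replicate 2 and 430 without Estrus replicate 4; of the 23 named genes past the threshold 7 kept their call in all 7 such fits (Ccnf, Nwd2os, Cfap69, Dnah1, Lca5, Esr1 and Usp18), and Gper1 kept it in those without Proestrus replicate 1 and without Estrus replicate 4 alone.

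Estrus was also compared with metestrus, where few single genes differed. Amigo2 (ENSMUSG00000048218.7), a neuronal adhesion protein that is also counted among A1 reactive astrocyte genes, was 3.23-fold lower in estrus at 5.62 ± 0.67 (SD, n = 4) against 7.29 ± 0.30 (SD, n = 8). Lrrc8c (ENSMUSG00000054720.13), a subunit of volume-regulated anion channels, was 2.62-fold lower at 6.41 ± 0.19 (SD, n = 4) against 7.82 ± 0.15 (SD, n = 8). Their adjusted p-values were 0.0468 and 0.0310, or 0.179 and 0.178 with the removed directions counted. Esr1 stood at -0.36 ± 0.64 (SE, adjusted p = 0.873), Gper1 at 2.84 ± 1.07 (SE, adjusted p = 0.318), Esr2 at 1.37 ± 1.45 (SE, adjusted p = 0.764). The values were for Pgr -0.13 ± 0.23 (SE, adjusted p = 0.868), Gfap 0.15 ± 0.20 (SE, adjusted p = 0.827) and Aldh1l1 0.00 ± 0.21 (SE, adjusted p = 0.997). In limma 18 genes passed, 4 higher and 14 lower, and 2337 had an unadjusted p under 0.05.

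At the level of gene lists, oligodendrocyte markers were higher in estrus than in metestrus, with 12 of 12 positive at a median of 0.33 and examples in Mog (0.89) and Cnp (0.58). Singly 0 passed over all genes or adjusted over the list alone. camera gave an adjusted p of 0.00226, and of 0.896 with an estimated correlation. Glycolysis and glycogen genes were higher too, 19 of 23 at a median of 0.22 with Pfkp at 0.57, Pkm at 0.52 and Pgam1 at 0.43 (adjusted p = 0.00226, and adjusted p = 0.896 with an estimated correlation), with 0 past the threshold singly by either adjustment. Cytosolic ribosomal protein genes were lower, 55 of 63 at a median of -0.15 with Rpl34 at -0.35 and Rps10 at -0.29 (adjusted p = 0.00526, and adjusted p = 0.896 with an estimated correlation), again with 0 past the threshold singly by either adjustment. In the same libraries nuclear-retained long non-coding RNAs had a median change of -2.62, with Malat1 at -2.09, Meg3 at -2.63, Miat at -3.47 and Kcnq1ot1 at -3.75 (adjusted p = 0.0686), Mirg at -2.62, Neat1 at -0.85 and Rian at -0.11. Of the 7, 5 had an unadjusted p under 0.05 and 0 passed the threshold in limma. The camera adjusted p of that set, chosen after the data were seen, was 1.47e-06 over the 6 contrasts, and 0.114 with an estimated correlation. The X-inactivation RNA Xist stood at -2.83 ± 0.82 (SE, adjusted p = 0.188).

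In estrus against metestrus 0 genes passed in limma with the removed directions counted and 0 within batches 2 and 3 alone (1657 had an unadjusted p under 0.05), and 5 passed with libraries centred on their medians, 3 higher and 2 lower (4930540M05Rik, Ppp1r3b, Slfn2, Arl11 and D930048N14Rik, named after their values were seen), with an adjusted p of 0.106 for the ribosomal list. The count was 0 without Metestrus replicate 1 or Estrus replicate 2, 44 without Estrus replicate 4, 56 without Metestrus replicate 3 and 10, 5, 8, 6 and 9 without Metestrus replicates 4, 5, 6, 7 and 8; Amigo2 lost its call in 11 of 12 such fits and Lrrc8c in 6, the oligodendrocyte list without Metestrus replicate 3 (adjusted p = 0.158) and the ribosomal list without Metestrus replicate 2 (0.132), Metestrus replicate 3 (0.158) or Estrus replicate 4 (0.293).

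A joint test of the 3 female stages asked which genes differed between any of them. In limma 254 genes passed, 72 of them (28.3%) with an average log2 CPM of at least 1, and 3325 had an unadjusted p under 0.05. Among the named genes Usp18, Ccnf and Nwd2os had their lowest group mean in proestrus, at 0.53, 2.29 and 3.05, and Zfp174 and Bcl9l their highest, at 7.95 and 9.96. The count was 57 with the removed directions counted and 1, Slfn2, within batches 2 and 3 alone. It was 93 without Proestrus replicate 1, 144 without Proestrus replicate 2 and 431 without Estrus replicate 4.

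Males were compared with metestrus females within batch 4, the batch they share. Sex-linked transcripts differed most: Xist (ENSMUSG00000086503.6) was 67.2-fold lower in males at 2.74 ± 2.19 (SD, n = 4) against 8.82 ± 0.68 (SD, n = 8). Its log2 fold change was -6.07 ± 0.71 (SE, adjusted p = 0.000534), and -6.86 to -5.17 when single libraries were left out. The Y-linked genes Ddx3y (ENSMUSG00000069045.12), an RNA helicase, Uty (ENSMUSG00000068457.15), Kdm5d (ENSMUSG00000056673.15), a histone demethylase, and Eif2s3y (ENSMUSG00000069049.12), a translation initiation factor, were higher by 6.53 ± 0.86, 6.24 ± 0.76, 5.42 ± 0.72 and 5.58 ± 0.74 (SE), with adjusted p-values from 0.000534 to 0.000827. In males they averaged 8.08 ± 0.48, 6.72 ± 0.60, 6.40 ± 0.27 and 6.83 ± 0.20 (SD, n = 4), against 1.55 ± 1.69, 0.46 ± 1.02, 0.96 ± 0.98 and 1.22 ± 1.24 in metestrus (SD, n = 8). These 5 were the only genes of 20644 past the threshold in limma with all libraries fitted. The lower group mean of each lay below the minimum of 3.32, so the sizes of these changes are uncertain. An unadjusted p under 0.05 was held by 1100, fewer than the medians of 1508.5 to 1857 in simulations of unchanged groups with independent genes. Next in order of p, without passing, were ENSMUSG00000126246 (1.44, adjusted p = 0.0567), Gm16277 (3.46, adjusted p = 0.0965), the growth factor betacellulin Btc (3.83 ± 0.75 SE, adjusted p = 0.117), the serotonin receptor Htr6 (1.87 ± 0.37 SE, adjusted p = 0.117) and Gm21586 (-3.15, adjusted p = 0.281). The lower group means of Btc and Gm21586 also lay below 3.32. This fit takes its spread from all 3 batches. With batch 4 fitted alone in limma 1495 genes had an unadjusted p under 0.05 and 6 passed. Htr6 was among these 6 (SE 0.26, adjusted p = 0.0191), but not with the title numbers as blocks (adjusted p = 0.177).

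**Figure D2:**
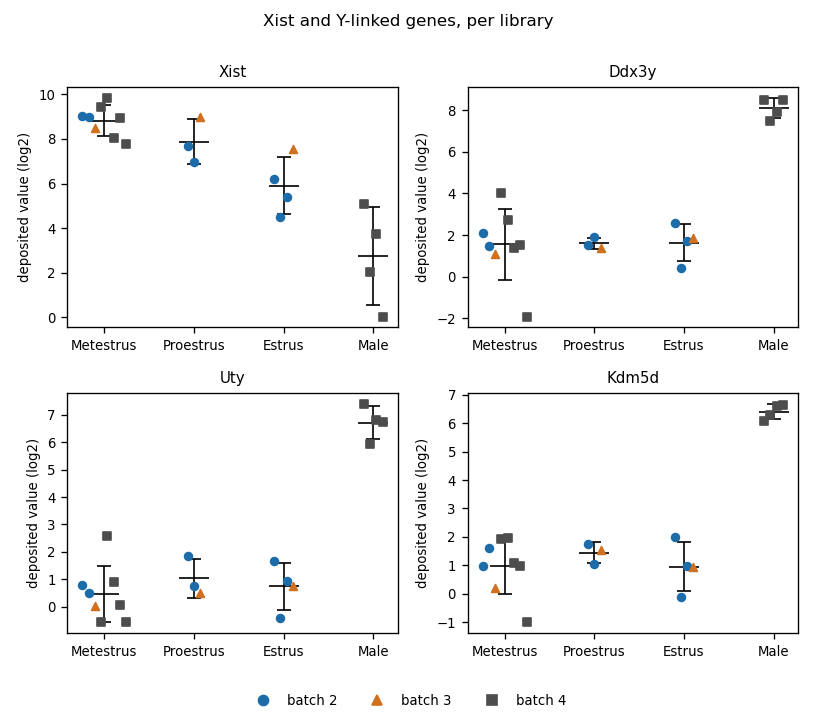
Deposited log2 values of Xist and of the Y-linked genes Ddx3y, Uty and Kdm5d in each library (points, shaped by batch), by group on the horizontal axis, with group means (bars) and SD (error bars). The 4 male libraries lie above every female library for each Y-linked gene, and Xist averages 2.74 in males and 5.91 in estrus.

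Immediate early genes, the transcription factors and regulators induced within minutes of stimulation, were higher in males than in metestrus females as a list. All 22 measured were positive at a median of 0.76, with Fos at 1.61 ± 0.49 (SE), Arc at 1.51 ± 0.54 (SE), Nr4a1 at 1.37 ± 0.50 (SE) and Egr1 at 0.97 ± 0.32 (SE). Singly 0 passed over all genes and 7 rose adjusted over the list alone (adjusted p = 0.0415 each), with 13 at an unadjusted p under 0.05. The list had an adjusted p of 6.49e-12 in camera, of 0.0952 with an estimated correlation and of 0.0947 in fry. Within batch 4 the mean of the list was 9.62 ± 0.62 in males (SD, n = 4) and 8.87 ± 0.44 in metestrus (SD, n = 5), a difference of 0.74 with a two-sided exact permutation p of 0.0952 (0.556 adjusted over the 35 lists).

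Reactive astrocyte and cytoskeletal genes were also higher in males as lists. Of 11 pan-reactive astrocyte genes 10 were positive at a median of 0.57, among them Hspb1 (0.74) and Osmr (1.96). Singly 0 rose over all genes and 1 adjusted over the list alone, the filament gene Gfap at 0.70 ± 0.18 (SE, adjusted p = 0.650 over all genes and 0.00762 over the list alone). The camera adjusted p was 0.000694, and 0.0952 with an estimated correlation, and the exact permutation p of the list mean within batch 4 was 0.0952 (0.556 adjusted over the lists). Of 25 process and cytoskeleton genes 21 were positive at a median of 0.20, and 0 rose over all genes and 2 adjusted over the list alone, Gfap and the actin-binding profilin Pfn1 (0.43). That list had an adjusted p of 0.000154, and of 0.271 with an estimated correlation. Its mean within batch 4 was 12.03 ± 0.08 in males (SD, n = 4) and 11.84 ± 0.09 in metestrus (SD, n = 5), with an exact permutation p of 0.00794, the smallest that 126 splits can give (0.0926 adjusted over the lists). The Y-linked list, far apart between the sexes, had the same permutation p and adjusted p. The adjusted value therefore does not decide. The astrocyte markers (18 of 22 positive, median 0.15, adjusted p = 0.0124) and cholesterol synthesis genes (18 of 24 positive, median 0.20, adjusted p = 0.0300) were higher. The cytosolic ribosomal protein genes (43 of 63 negative, median -0.03, adjusted p = 0.0349) were lower, and all 3 lists had an adjusted p of 0.966 with an estimated correlation. The exact permutation p of their means within batch 4 was 0.254, 0.294 and 0.690. Singly 0 of these passed over all genes, and adjusted over the list alone 2 astrocyte markers rose, Gfap and the transcription factor Sox9 (0.47). Endothelial and mural markers (11 of 14 positive, median 0.43) and meningeal fibroblast markers (6 of 9, median 0.31) had camera adjusted p-values of 0.114 and 0.0718. Neuron markers had a median change of 0.0145. The Y-linked list had an adjusted p of 2.15e-22, and of 0.00184 with an estimated correlation. X-linked genes that escape inactivation were lower, 5 of 5 at a median of -0.52 (adjusted p = 1.17e-09, and 0.00184 with an estimated correlation), with 1 falling over all genes, Xist, and 3 adjusted over the list alone, with Ddx3x (-0.58) and Eif2s3x (-0.51).

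For males against metestrus the count of 5 was the same with the removed directions counted, and it was 8 without Male replicate 2; the astrocyte, cholesterol and ribosomal lists had adjusted p-values of 0.0555, 0.0555 and 0.108 with batch 4 fitted alone. The astrocyte list was also lost without Metestrus replicate 4 (0.0527), Metestrus replicate 5 (0.112) or Male replicate 2 (0.0938), the cholesterol list without Metestrus replicate 4 (0.383), Male replicate 1 (0.0517) or Male replicate 4 (0.0948), and the ribosomal list without Metestrus replicate 4 (0.804), 7 (0.438) or 8 (0.0654) or Male replicate 1 (0.772), 2 (0.181) or 3 (0.639).

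**Figure D3:**
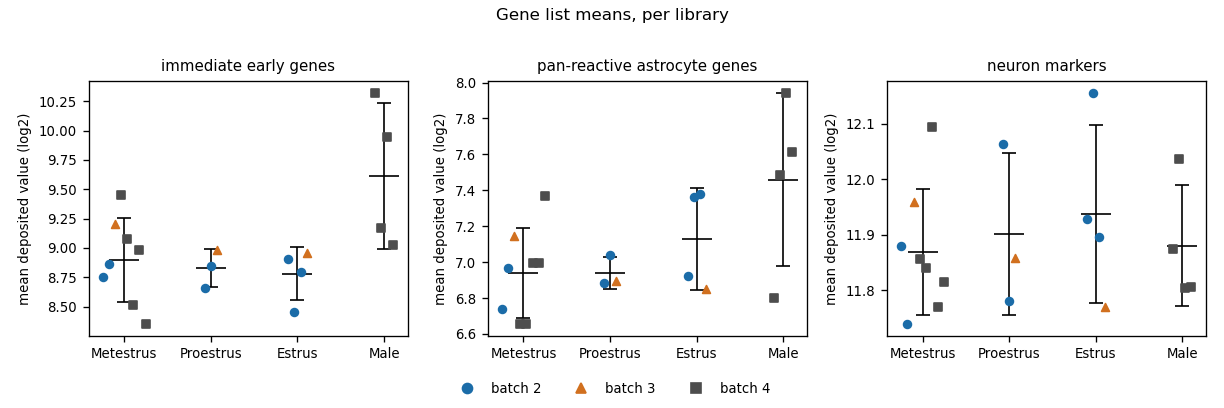
Mean deposited log2 value of the immediate early genes, the pan-reactive astrocyte genes and the neuron markers in each library (points, shaped by batch), by group on the horizontal axis, with group means (bars) and SD (error bars). Immediate early genes average 9.62 in males and 8.90 in metestrus with overlapping libraries, and neuron markers 11.88 and 11.87.

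Males were set against proestrus and estrus females, with which they share no batch. Each change is therefore that of males against metestrus minus that of the stage against metestrus. The results are not independent of those contrasts. Ccnf was 21.6-fold higher in males than in proestrus, at 6.65 ± 0.15 (SD, n = 4) against 2.29 ± 0.70 (SD, n = 3), with an adjusted p of 0.0151 and of 0.0621 with the removed directions counted. Its proestrus mean lay below the minimum of 3.32, so the size of this change is uncertain. The same holds for Nwd2os, Xist and the Y-linked genes below, which also had a group mean under that minimum. Angpt1, angiopoietin 1, a ligand that steadies blood vessels, stood 3.16 ± 0.60 higher (SE, adjusted p = 0.0270). Also higher were Lca5 by 3.59 ± 0.65 (SE, adjusted p = 0.0236), Zfp747l1 3.08 ± 0.55 (SE, adjusted p = 0.0236) and Nwd2os 3.02 ± 0.57 (SE, adjusted p = 0.0270). With the removed directions counted these 4 had adjusted p-values of 0.105 (Angpt1), 0.0801 (Lca5), 0.105 (Zfp747l1) and 0.127 (Nwd2os). Erbb2, a receptor tyrosine kinase, was lower in males at 4.19 ± 0.66 (SD, n = 4) against 7.34 ± 0.47 (SD, n = 3), with an adjusted p of 0.0393 (0.154 with the removed directions counted), and Dennd4b fell by 1.56 (SE 0.32, adjusted p = 0.0464, and 0.159 with the removed directions counted). In limma 36 genes passed, 28 higher and 8 lower in males, with 2291 at an unadjusted p under 0.05. The Y-linked genes, higher by 6.48 (Ddx3y), 5.65 (Uty), 4.89 (Kdm5d) and 5.34 (Eif2s3y), had adjusted p-values of 0.0549 to 0.0789 over all genes, and 4 of 4 rose adjusted over the list alone. Xist stood at -5.11 ± 1.13 (SE, adjusted p = 0.0632). The immediate early genes were positive in 22 of 22 at a median of 0.72, with 0 past the threshold singly by either adjustment (adjusted p = 0.00457, and 0.991 with an estimated correlation). The lists of Y-linked and of X-linked escape genes passed too, with adjusted p-values of 4.40e-07 and 0.00639, and of 0.201 and 0.205 with an estimated correlation. The count was 7 with the removed directions counted, 16 without Proestrus replicate 1, 10 without Proestrus replicate 3, 14 without Male replicate 3 and 7 without Male replicate 4; each of the 7 named genes lost its call in 2 to 6 of the 7 such fits, and the immediate early list lost it without Male replicate 1 (adjusted p = 0.0640).

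Between males and estrus females 0 genes passed in limma, with 2138 at an unadjusted p under 0.05 and a smallest adjusted p of 0.115. That value was shared by Amigo2 (2.32 ± 0.44 SE), Lrrc8c (1.74 ± 0.33 SE), Mgll (1.24 ± 0.24 SE), the lipase that breaks down the endocannabinoid 2-arachidonoylglycerol, and Neurl3 (5.81). It was also that of Gm49502 (7.18), Rad51b (-4.31), Foxd2os (-5.34), the proliferation marker Mki67 (5.92) and the Y-linked Uty (5.98), Kdm5d (5.42), Ddx3y (6.47) and Eif2s3y (5.55). Xist stood at -3.24 ± 1.08 (SE, adjusted p = 0.321). Immediate early genes were higher in males, 20 of 22 at a median of 0.60 (adjusted p = 0.000498, and 0.743 with an estimated correlation), with 0 rising over all genes and 3 adjusted over the list alone, Egr3 (1.63), Jund (1.0) and Egr1 (1.48). The Y-linked list (adjusted p = 8.55e-09, and 0.0985 with an estimated correlation) and the X-linked escape list (0.0187, and 0.335) passed as well. Genes for potassium, water and gap junctions (13 of 15, median 0.33), synapse-modulating factors (17 of 21, median 0.38), astrocyte markers (21 of 22, median 0.24) and cholesterol synthesis (21 of 24, median 0.33) were higher in males, each with an adjusted p of 0.0411, and of 0.743 with an estimated correlation. Oligodendrocyte markers were lower in males, 9 of 12 at a median of -0.38 (adjusted p = 0.0213, and 0.700 with an estimated correlation). Singly 0 of these genes passed over all genes, and adjusted over the list alone 1 synapse-modulating factor rose, Bdnf (1.77). The nuclear-retained RNAs stood 2.46 higher in males at the median (camera adjusted p = 0.000350 over the 6 contrasts, and 0.195 with an estimated correlation). In limma's fry for mixed directions the A1 reactive astrocyte and estrogen-responsive lists passed (adjusted p = 0.0223 each).

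The count of 0 for males against estrus became 1 without Estrus replicate 1 (Amigo2), 1 without Estrus replicate 4 (Mki67) and 4 without Male replicate 3 (Gm26920, Gm37899, Kcnq1ot1 and Gm49502), some of them named after their values were seen. Apart from the immediate early and Y-linked lists, the lists lost their call in some of these fits: the X-linked list without Estrus replicate 1 (adjusted p = 0.0518), the oligodendrocyte list without Estrus replicate 3 (0.0649) or Male replicate 3 (0.102), the cholesterol list without Estrus replicate 3 (0.0598), Estrus replicate 4 (0.476), Male replicate 3 (0.0810) or Male replicate 4 (0.0730), and the astrocyte, potassium and synapse lists without Estrus replicate 2 (0.0549, 0.0685 and 0.0549), Estrus replicate 4 (0.593, 0.476 and 0.444), Male replicate 2 (0.0908, 0.102 and 0.102) or Male replicate 3 (0.0810 each), with the astrocyte list also lost without Male replicate 1 (0.0528).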

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

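The tests of neuronal RNA and of batch for the immediate early genes, the fit with unequal spread and counted directions and the count of genes below the minimum for the stage genes, and the splits within batches were chosen only after the results were seen.

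Most genes past the threshold in proestrus against metestrus were lower in proestrus (156 of 204), with a median change of -3.69 among these. Without Metestrus replicate 3 the calls were 84 higher and 89 lower, so the imbalance leaned on that library. A general loss of scarce transcripts from the proestrus libraries stays open. The planned test took the 7031 scarce genes that were not called (median change -0.19), and cannot decide because it leaves out the called genes. Proestrus libraries held 451 more tested genes below the minimum than metestrus libraries of the same batch (SE 104), and up to 156 of these could be the called genes themselves. Estrus libraries held 334 more than metestrus as well (SE 97.5), although 18 genes were called there, so the excess is not particular to proestrus and does not decide. Residual spread was larger in batches 2 and 3 than in batch 4 for the 204 genes (medians 0.93 and 0.64) and less so for all 20644 (0.47 and 0.41). With spread allowed to differ by a factor shared by all genes, and the removed directions counted, 57 of the 204 still passed, 44 lower and 13 higher. A shared factor may correct too little for the 204 genes, whose gap in spread was wider, so this fit does not exclude unequal spread. For the other 147 the wider errors ended the call whether or not a gene changed, and unequal spread cannot be told apart from a stage effect. A change with the stage of the cycle stays open as a hypothesis, as do differences in handling that the labels do not record.

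Splits of the same libraries were counted with the real one included. Of 100 splits, 3 gave a count at least as large for proestrus against metestrus (real 204, highest other 393), 2 for estrus against metestrus (real 18, highest other 60), 2 for males against metestrus (real 5, highest other 6) and 1, the real one, for any stage (real 254, highest other 163). For males against proestrus 1 of 35 did, again the real one (real 36, highest other 1). Of splits that keep the size of each group in each batch, 3 of 100 did for males against metestrus (real 5, highest other 111) and 1 of 100, the real one, for any stage (real 254, highest other 135). These shares lie under 0.05. For estrus against proestrus 2 of 35 splits did (real 194, highest other 317), so chance is not excluded there. For males against estrus the real count was 0 (highest other 1), which all 35 of 35 splits reach by necessity, so nothing was tested. The values lack directions that were taken out with the real groups kept, so these comparisons favour the real split, and chance is not held to be excluded by the small shares either. Why some splits call more genes than the real one was not tested.

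Immediate early genes had a median of 0.76 above metestrus in males. A larger share of neuronal RNA would raise neuron markers alike, and their median change was 0.0145 on the log2 scale. These markers follow the share of neuronal RNA, and do not show in which cells the immediate early genes changed. These fold changes rest on batch 4 alone by the design, so the median within it (0.76) equals the main one and tests nothing about batch. The pattern did not rest on a single male library: the lowest median without 1 of them was 0.53, without Male replicate 1, and the others ranged from 0.65 to 1.0. The time of day and the handling of the males are confounded with sex and stay open, as does sex itself, which may account for the difference but was not tested apart from them.

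Single libraries that lay far from the rest of their group were found in 19 of 285 group tests, where about 14.25 would be expected by chance. The 3 proestrus libraries were too few for this test and were left out of it. In Male replicate 2 the back-transformed total was 2.23e7 (others 2.51e7 to 2.56e7) and 2956 genes lay below the minimum (others 3192 to 3235). In Metestrus replicate 3, the sole metestrus library of batch 3, 2495 genes lay below it (others 2998 to 3371) and Rad51b was high at 3.72 (others 1.49 to 2.33). Metestrus replicate 4 had a high mean of choroid plexus and ependymal markers at 7.21 (others 3.89 to 5.41) and a low mean of process and cytoskeleton genes at 11.70 (others 11.82 to 11.92). Ribosomal protein genes averaged 12.68 in Male replicate 4 (others 12.19 to 12.27), where Htr6 stood at 6.85 (others 7.17 to 7.23). Estrus replicate 4 had a high mean of interferon genes at 7.64 (others 7.40 to 7.43) and Mki67 at 4.03 (others -1.69 to -1.07). In Metestrus replicate 5 the X-linked escape genes averaged 10.47 (others 9.87 to 10.13) and Uty stood at 2.58 (others -0.57 to 0.89). Esr1 was low in Estrus replicate 3 at 4.46 (others 6.38 to 6.51), and Frmd3 high in Estrus replicate 1 at 7.80 (others 6.36 to 6.48). Pcdh15 was low in Metestrus replicate 6 at 5.10 (others 5.76 to 6.10) and in Male replicate 3 at 6.16 (others 6.50 to 6.54), and Gm21586 high in Male replicate 3 at 4.77 (others 0.72 to 1.28). Trmt44 was low in Male replicate 1 at 5.74 (others 6.39 to 6.51), and Gm49502 in Estrus replicate 2 at -3.27 (others -1.03 to -0.69).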

How the results depend on the processing

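The fits with removed directions, median centring, quantile normalization, library weights and batch-specific spread were chosen after seeing the data. Counts below run in the order proestrus, then estrus, against metestrus, estrus against proestrus, males against metestrus, proestrus and estrus, and any stage, and name a contrast only where the count moved by more than 1.5 times. A count that moved less can still hold other genes. Without Metestrus replicate 2, 12 genes passed in estrus against metestrus, and 3 of them were among the 18 of the full fit. Counts of named genes: all 56 called kept their direction in every setting that could be run. Some settings, such as batches 2 and 3 alone, left fold changes identical by construction. The 56 were also chosen for passing in these same values, so a kept direction adds little support. A looser threshold of 0.1 gave 418, 68, 619, 114 (males against proestrus) and 745 (any stage). With an average log2 CPM of at least 1, where fewer genes were tested, they were 24, 0, 51, 1, 2 (males against proestrus) and 26 (any stage). With batch-specific spread they were 91, 0, 61, 9 and 92 (any stage), and with the removed directions counted as well 57, 0, 45, 5 (males against proestrus) and 45 (any stage). The removed directions alone with group and batch gave 75, 0, 52, 7 (males against proestrus) and 57 (any stage), with 26 of 56 named genes still past. With group and removed directions but no batch the counts were 54 (estrus against metestrus), 33 (estrus against proestrus), 408 and 294 (males against proestrus and estrus). Without batch they were 1146, 899, about 3.6e2 (217 higher, 144 lower), 10, 1752, 1974 and 1825, and in simulated unchanged groups with batch effects that model gave medians of up to 1503.5 false calls. Batches 2 and 3 alone, with fewer libraries, gave 1, 0, 0 and 1 (any stage), with 1912, 1657, 2249 and 2206 at an unadjusted p under 0.05 and 0 of 44 named genes past. Batch 4 alone gave 6 for males against metestrus, and 4 with the title numbers as blocks, where Xist was lost (-6.04 ± 1.19 SE, adjusted p = 0.787, against -6.07 ± 0.80 without them); residual correlations of -0.26 to 0.16 between equal numbers do not show that these pair libraries. Fits of only the compared groups gave 0 (estrus against proestrus), 1392 and 813 (males against proestrus and estrus, where batch cannot be fitted) and 143 (any stage). Library weights, which did not converge, gave 419, 0, 691, 534, 396 (males against proestrus) and 694 (any stage). Median centring gave 5 (estrus against metestrus) and about 3.0e2 (estrus against proestrus, 184 higher and 118 lower), and quantile normalization 4 (estrus against metestrus), 18 (males against proestrus) and 1, Mgll (males against estrus). Of 210 pairs of list and contrast 22 passed camera, 2 with an estimated correlation and 4 in fry for 1 direction. Leaving out 1 library gave 68 (Metestrus replicate 1) to 190 genes, 0 (Metestrus replicate 1) to 56 (Metestrus replicate 3), 66 (Proestrus replicate 1) to 430 (Estrus replicate 4), 5 to 8 (Male replicate 2), 7 (Male replicate 4) to 37, 0 to 4 (Male replicate 3) and, for any stage, 93 (Proestrus replicate 1) to 431 (Estrus replicate 4), and, of 105 pairs of list and contrast each, 3 (without Proestrus replicate 1 or 2, where the full fit also gave 3) to 26 lists (without Male replicate 4, where the full fit gave 19). Changes that turned in sign, none past the threshold, are given with the other end of their range over left-out libraries. In proestrus against metestrus they were Gfap (0.10 without Metestrus replicate 3, -0.29 without Metestrus replicate 1) and Aldh1l1 (0.0241 and -0.16 without the same libraries). Esr2 turned with quantile normalization (0.23), library weights (0.20) or without Metestrus replicate 1 (0.83, against -1.56 without Metestrus replicate 3). In estrus against metestrus they were Esr1 (0.19 without Estrus replicate 3, -0.94 without Estrus replicate 4) and Pgr (0.0508 without Metestrus replicate 1, -0.43 without Metestrus replicate 2). Aldh1l1 turned there with quantile normalization (-0.00151) or without Metestrus replicate 1 (-0.0582), Metestrus replicate 2 (-0.0283), Estrus replicate 2 (-0.0121) or Estrus replicate 3 (-0.13), against 0.14 without Estrus replicate 4. In estrus against proestrus Aldh1l1 turned without Estrus replicate 3 (-0.0302, against 0.24 without Estrus replicate 4). Except where stated, the cause was not tested. DESeq2, limma-voom, other size factors and svaseq were not run, because the values are not counts, and a minimum fold change of 0.5 log2 units changed no count. Unknown depth keeps counting error out of all estimates.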

Other observations

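The test of male tissue among the estrus libraries and the set of nuclear-retained RNAs were chosen only after the change of Xist was seen, and the outcome for that set was not known when it was written down.

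Further genes stood out in estrus when adjusted over the list alone, without passing over all genes. Vegfa, the vascular growth factor, was -1.23 ± 0.27 (SE) against metestrus, with an adjusted p of 0.0830 over all genes and 0.00408 over the 22 estrogen-responsive genes alone. In the same list the retinoic acid receptor Rara was -0.83 ± 0.25 (SE, adjusted p = 0.202 over all genes). Bdnf, a neurotrophin, was -1.01 ± 0.29 (SE, adjusted p = 0.185 over all genes and 0.0451 over its list alone). The oligodendrocyte precursor genes Lhfpl3 and Olig2 were -1.74 ± 0.35 (SE, adjusted p = 0.0533) and -0.93 ± 0.29 (SE, adjusted p = 0.224), while markers of mature oligodendrocytes were positive in 12 of 12. Irf7, an interferon-induced transcription factor, was -3.20 ± 0.87 (SE, adjusted p = 0.158). The hormone gene Gh was 4.07 ± 1.35 (SE, adjusted p = 0.258), with a mean of 4.17 ± 2.96 in estrus (SD, n = 4) and 0.24 ± 0.61 in metestrus (SD, n = 8).

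Clock genes as a list did not pass in any of the 6 contrasts, with medians of -0.15 in proestrus and 0.12 in estrus against metestrus (camera adjusted p = 0.984 and 0.308) and of 0.06 in males against metestrus (0.973). Mitochondrial DNA genes had medians of -0.18 and -0.28 in proestrus and estrus against metestrus and of 0.23 in males (camera adjusted p = 0.916, 0.633 and 0.338). In the fibroblast marker list, Col1a1 and Col3a1 were 1.5 ± 0.42 and 1.85 ± 0.62 (SE) higher in males than in metestrus, with adjusted p-values of 0.691 and 0.818 over all genes and 0.0159 and 0.0323 over the list alone.

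Xist fell short of the threshold in estrus against metestrus but stood at 5.91 ± 1.29 (SD, n = 4) against 8.82 ± 0.68 (SD, n = 8), a change of -2.83 that ranged from -3.57 to -2.46 when single libraries were left out. Male tissue or a swapped male library is excluded, since the highest estrus library lay 4.67 log2 units below the lowest male library in the mean of the Y-linked genes (1.99 and 6.66). A candidate explanation is that less nuclear RNA was carried into the estrus pulldowns. The median change of 7 other nuclear-retained RNAs was -2.62 (SE 0.50 over the members), past the bound of -1.42, although Neat1 (-0.85) and Rian (-0.11) moved less. This SE is too small, because it treats the members as independent and their estimated correlation was 0.49. With that correlation the camera adjusted p of the set was 0.114. The mean of the 7 ranged from 5.64 to 8.93 among the estrus libraries and from 9.16 to 10.29 in metestrus. Low values were not confined to estrus: Proestrus replicate 2 stood at 7.42 and Male replicate 3 at 8.0, and the median change in proestrus against metestrus was -0.88. Whether the estrus values reflect handling of the estrus samples or a change in the cells with the stage was not tested, and stays open. If nuclear RNA differed between pulldowns, other changes in estrus could share that source, which the present values do not separate.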
